A study of Mus musculus with 4 samples.

How the data were processed

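Tumour culture DNA (channel 1) and tail DNA of the same animal (channel 2) of 4 KPC mice were hybridised to Agilent 244K mouse comparative genomic hybridisation arrays, 1 array per mouse. Per the labels, cultures were grown in medium with 10% serum for fewer than 10 passages, and 250 ng of DNA was labelled. The scanner files were written by Agilent Feature Extraction 10.7.3.1. Per the file headers, their log10 column is the log10 of the red (Cy5) over the green (Cy3) processed signal, which was checked against the signals. Per the file headers, processed signals are an intensity, background-subtracted and scaled with linear dye factors, and the raw median spot and background signals are an intensity without correction. The value table deposited by the authors gives a score that was found, by comparison with the scanner ratios, to be log2 Cy5 over Cy3 minus 1 constant per array. This held within 0.001 for 99.86%, 99.85%, 99.93% and 99.89% of the compared cells in arrays 1 to 4. It covers chromosomes 1 to 5 only (65522 probes), 5 of its cells lost their decimal point, and how the authors chose the constants is not given in the sources used here.

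Positions were those of mm9. The file of array 3 gives mm8 positions, so its probes took the mm9 positions of the same probes in the other files. Of 233412 probes placed on chromosomes 1 to 19 and X, 233171 not marked as faulty on any array were kept (279, 218, 180 and 171 spots were marked in arrays 1 to 4). Log ratios were turned to log2 and centred on the median of each array. Signals not well above background numbered 1148, 827, 155 and 444 spots in Cy5 and 1175, 634, 127 and 276 in Cy3. Probes printed as triplicates had a root mean square SD of 0.0998, 0.108, 0.0568 and 0.0937 on the log2 scale, which with the 4 mice sets the precision.

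Each chromosome was segmented by penalised least squares (PELT) in probe order, with a penalty of 5 times the log of the number of probes times the noise variance, at least 5 probes per segment, and values pulled in to 3 noise SDs of a running median over 11 probes. Segments at least 0.25 from 0 were called. Bins of 1 Mb with at least 5 probes took the call of their segments. A chromosome counted as called as a whole when at least 90% of its bins were called with the same sign. Lower bounds of ratios near background replaced a Cy5 signal by the smallest processed signal that was well above background on the array. Outlying probes lay over 4 robust SDs from their segment mean.

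Means per bin and per chromosome were tested against 0 with limma 3.58.1 (intercept only, moderated variance, two-sided, Benjamini-Hochberg adjusted p under 0.05). Recurrence in at least 3 arrays and the correlation of profiles were tested against 1000 rotations of each array along the genome, and correlations were adjusted over the 6 pairs. Outlying probes were tested over all choices of 2 of the 19 autosomes by an exact permutation test. The channel that departs was found from the slope of each channel's log2 signal, less the same probe's mean in the other 3 arrays, on the segment mean, with an exact sign test.

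These comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 3 engineered loci, up to 30 list genes in called segments ordered by largest departure, and the 3 called segments under 3 Mb with the largest departure in each array. The lists were the engineered loci, tumour suppressors, oncogenes, families that vary between strains, and comparison genes. The files pair no probe with a gene and no annotation of mm9 was given, so gene-level limma, the count adjusted over the list alone and the genes of a segment could not be formed. In their place, limma was run per chromosome and each listed gene was placed on its chromosome with the GRCm38.p6 gene table, all 85 entries being found by symbol and no coordinates being used. Part of the result of the engineered loci and of the oncogenes is not reported here. No correction for GC content was run, since neither the genome nor probe sequences were given.

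Alternatives were normexp background correction with an offset of 50 (on median signals, as the files give no mean), the authors' values, other centrings, leaving out dim probes, penalties of 2.5 and 10, call thresholds of 0.15 and 0.40, at least 20 probes per segment, 5-Mb bins, array weights, outlier limits of 3 and 6 SDs, the opposite sign, and leaving out each array. Those chosen after seeing the data were the authors' constants applied to all probes, leaving out segments below -3, correlations within chromosomes, the whole-chromosome calls and list counts under other centrings, and every alternative for the chromosome means and for the 10-probe region. The steps were tested on simulated arrays with normal noise that was independent between probes. The real arrays vary along the chromosomes too, so the rates below need not hold for them. Segments of 10 probes at -4 and of 100 probes at -0.75 or 0.50 were called over 100% of their probes, segments of 1000 probes at -0.35 over 99.9%, and segments at 0.10 over 0%. In 50 simulated sets each, the recurrence test passed in 2% without and 96% with a shared block. In 200 simulated sets each, the outlying-probe test passed in 3% without and 100% with planted probes. The planted excess was larger than the 0.184 percentage points found in the data, so the 100% gives no power for that size. Among 2551 simulated bins with 200 shifted, limma recovered 63% of those shifted by 0.30 and 100% of those shifted by 0.60, with 4.12% of calls false. These bins were independent. Their spread between mice was smaller than that of some real chromosomes (SD 0.34 on chromosome 4) and larger than that of others (0.06 on chromosome 1). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and R 4.3.3 were used.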

Results

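Genomic DNA from 4 primary pancreatic tumour cultures, each from a different KPC mouse, was compared with tail DNA of the same mouse on 4 two-colour comparative genomic hybridisation arrays. KPC mice are an engineered model of pancreatic cancer that carries, among other alleles, a conditional mutant Trp53 switched on in the pancreas by a Cre recombinase. The design holds 1 group of 4 mice with 1 array each, and each tail served as the control of its own culture. Each array held 238202 probe spots, and 233171 probes on chromosomes 1 to 19 and X were used, at a median spacing of 7858 bp. Median Cy5 signals were 545, 558, 885.5 and 669 in arrays 1 to 4, over local backgrounds of 100, 109, 131.5 and 123. Median Cy3 signals were 284, 324, 517 and 460, over backgrounds of 31.5, 25.5, 37 and 38. The noise between neighbouring probes had an SD of 0.121, 0.137, 0.135 and 0.178 on the log2 scale. With 4 mice, the number of arrays limited the precision of every mean.

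The labels contradict themselves on the dyes, since the channel labels put the culture in Cy5 and the labelling protocol puts the sample in Cy3. All values are therefore given as log2 Cy5 over Cy3, and higher and lower refer to that ratio. Over probes in called segments, the Cy5 signal moved with the segment mean, with slopes of 0.445, 0.486, 0.854 and 0.878 in arrays 1 to 4. The Cy3 slopes were -0.0249, -0.105, -0.0133 and -0.0164. Cy5 carried the larger part in 4 of 4 arrays, for which the exact two-sided sign test gave p = 0.125, the smallest possible with 4 arrays. Since the tail is the reference, this and the channel labels put the culture in Cy5 as the likely assignment, and a higher ratio as more DNA in the culture, against the labelling protocol.

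The first comparison asked how much of each culture's genome differed from its tail. Array 1 had chromosomes 6 and 16 higher and chromosomes 4, 12, 13 and 14 lower over at least 90% of their 1-Mb bins. Both higher calls of array 1 ended with centring on the mode, which left 49.7% of chromosome 6 and 25% of chromosome 16 called (means 0.24 and 0.23). Array 2 had chromosome 6 higher and chromosomes 12 and 14 lower, with chromosome 19 higher over 84.7% of its bins. Array 3 had chromosome 6 higher and no other whole-chromosome call. Array 4 had chromosomes 4, 7, 10 and 11 lower, with means of -0.76, -0.74, -0.75 and -0.41, and no chromosome called higher over 90% of its bins. Called segments covered 40.6%, 40.1%, 6.43% and 25.4% of the 2551 bins in arrays 1 to 4, a mean of 28.1% ± 16.1 (SD, n = 4), which was 42.1% at a call threshold of 0.15 and 14.1% at 0.40. Higher bins made up 12.9%, 17.7%, 6.15% and 0.431%, and lower bins 27.7%, 22.4%, 0.274% and 24.9%. No test was run between arrays, each of which is a separate mouse. With centring on the mode of the probe distribution, which lay 0.11 above the median in array 1 and 0.14 above it in array 4, the higher share of all calls was 21.8% in place of 33.1%, and with the sign turned to Cy3 over Cy5 it was 66.9%. That centring also put chromosome 9 of array 1 and chromosome 18 of array 4 among the chromosomes lower over at least 90% of their bins. Array 2 was split into 1262 segments, against 320, 109 and 174 in arrays 1, 3 and 4. Of its 570 called segments, 471 were under 3 Mb. Its uncalled bins also varied most within chromosomes, with an SD of 0.105, against 0.054, 0.038 and 0.076 in arrays 1, 3 and 4. How much of its 40.1% comes from such variation was not tested.

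**Figure D1:**
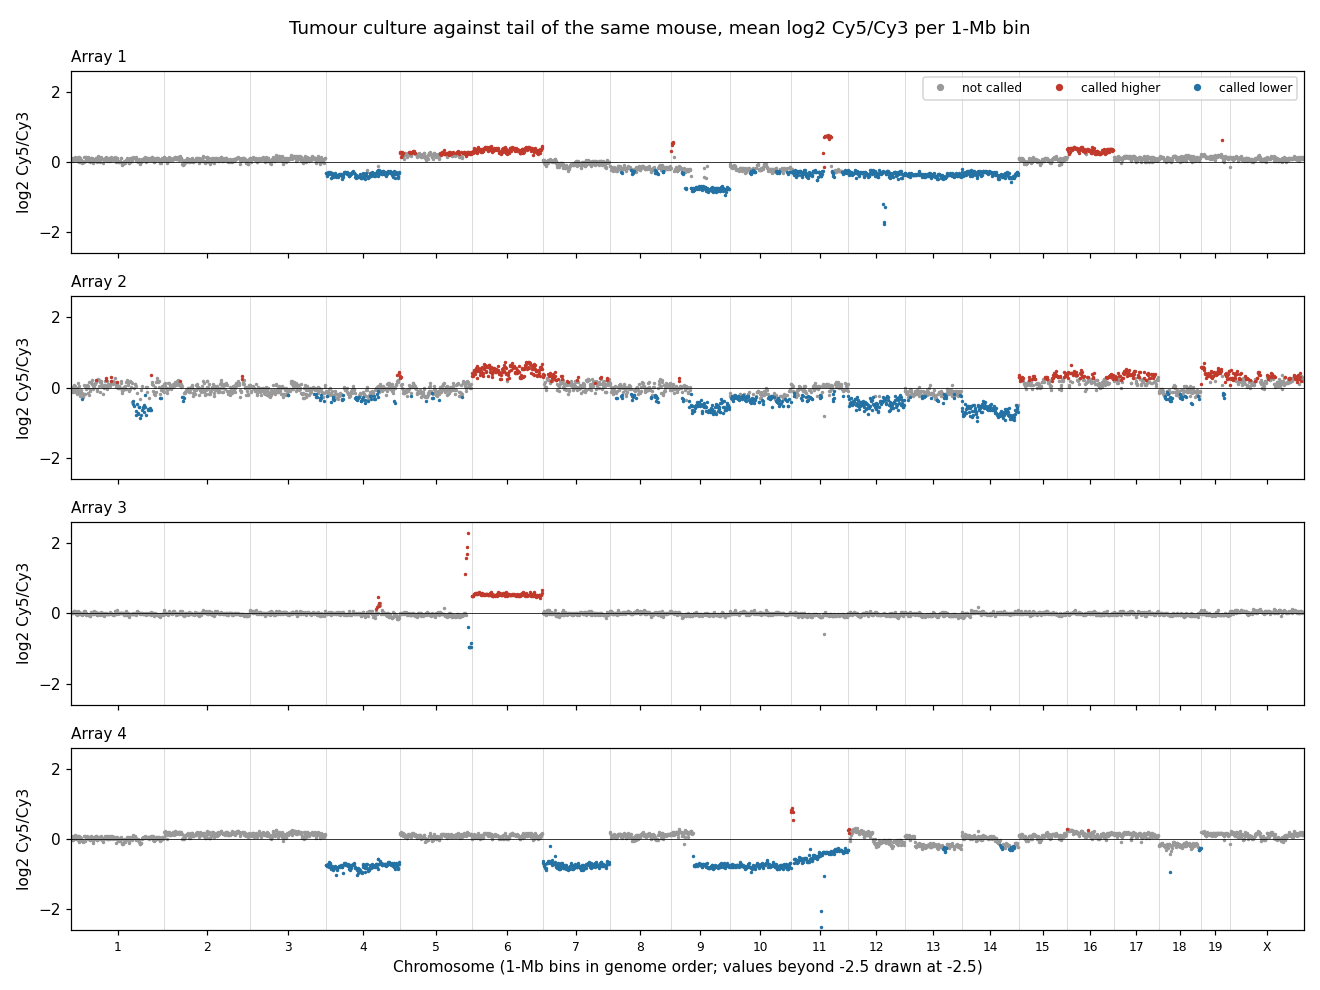
Mean log2 Cy5 over Cy3 of each 1-Mb bin (vertical axis, log2 units) in genome order (horizontal axis) for the 4 arrays, each point being a bin in a segment called higher, called lower or not called, and values below the axis drawn at its lower edge. Chromosome 6 is called higher in arrays 1, 2 and 3 and not in array 4, and array 3 has calls over 6.43% of its bins.

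The second comparison asked which chromosomes and regions differed from the tail in the same way across the mice. Chromosome 6 was higher, with means of 0.35, 0.51, 0.53 and 0.10 in arrays 1 to 4 and a mean of 0.37 ± 0.20 (SD, n = 4). The 0.10 of array 4 is below the 0.14 by which its mode exceeded its median, so its sign turns with that centring, and none of its chromosome 6 bins was called. Chromosome 9 was lower, with means of -0.54, -0.38, -0.03 and -0.40 and a mean of -0.34 ± 0.22 (SD, n = 4). Lower calls covered 68.0%, 70.5% and 61.5% of chromosome 9 in arrays 1, 2 and 4 and none of it in array 3. These were the 2 of 20 chromosomes past the threshold in limma, with adjusted p = 0.0263 for chromosome 6 (higher in 4 of 4 arrays) and adjusted p = 0.0334 for chromosome 9 (lower in 4 of 4 arrays). Chromosome 4 (-0.30 ± 0.34, SD, n = 4) and chromosome 10 (-0.30 ± 0.32) followed, each with a limma adjusted p of 0.0992, and 6 chromosomes had an unadjusted p under 0.05. No chromosome passed limma when array 1 or array 2 was left out (3 unadjusted in each case), 5 passed without array 3, and 4 passed without array 4. No chromosome passed either with centring on the mode or on the zero of the authors' values, where limma gave 5 and 3 at an unadjusted p under 0.05.

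**Figure D2:**
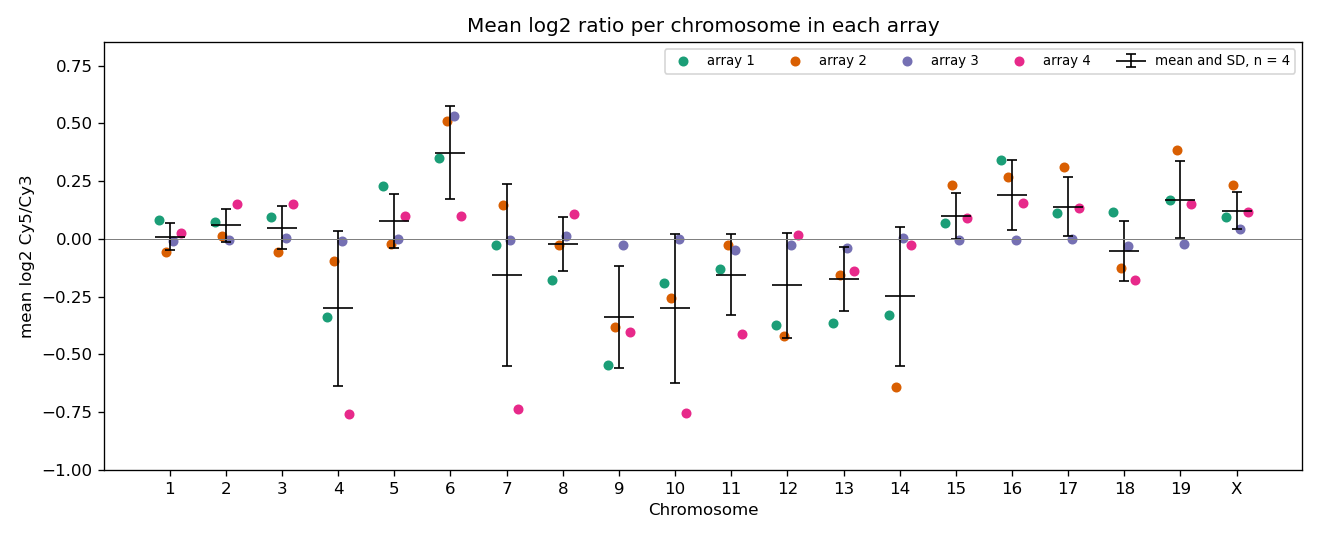
Mean log2 Cy5 over Cy3 of each chromosome (vertical axis, log2 units) by chromosome (horizontal axis), with a coloured point for each of the 4 arrays, a bar at their mean and whiskers of 1 SD (n = 4). Chromosome 6 has its mean at 0.37 and chromosome 9 at -0.34, and on chromosomes 4, 7 and 10 array 4 lies lowest, at -0.76, -0.74 and -0.75.

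At 1-Mb resolution, 319 bins were called with the same sign in at least 3 arrays, 147 of them higher and 172 lower, and none was called in all 4. The count was 582 at a call threshold of 0.15 and 75 at 0.40. The split depended on the centring, with 73 higher and 307 lower bins on the mode and 89 and 245 with the authors' constants. Chromosome 6 held 146 of the higher bins, out of its 147, in arrays 1, 2 and 3, and 73 with mode centring or 89 with the authors' constants. Chromosome 9 held 71 of the lower bins, all between positions 50000001 and 125000000 (mm9). The other lower bins lay on chromosomes 4 (35 bins), 11 (22), 10 (21), 14 (16) and 13 (7), and 1 higher bin lay on chromosome 16. With mode centring or the authors' constants, chromosome 10 held 79 or 65, chromosome 14 held 37 in each case, chromosome 13 held 24 or 9, and chromosome 12 held 20 or 13. Several rest on a small part of an array's chromosome, such as 22.9% of chromosome 4 in array 2, 16.5% of chromosome 10 in array 1 and 13.6% of chromosome 14 in array 4. Arrays 1, 2 and 4 also correlated along the chromosomes over uncalled bins (mean Pearson 0.672), which rotation does not keep. Rotating each array's calls along the genome gave a mean of 46.0 such bins and a 95th percentile of 144, and 319 was above all 1000 rotations (permutation test, one-sided, p = 0.001, the smallest that 1000 rotations can give). No single bin passed limma at an adjusted p under 0.05 (0 of 2551, smallest adjusted p 0.137), with 599 bins at an unadjusted p under 0.05. With arrays weighted by their fit, limma called 514 bins, 202 higher and 312 lower, array 1 having a weight of 3.14 and arrays 2 to 4 of 0.691, 0.745 and 0.619. Without array 3 it called 72, all lower, and without array 4 it called 429, while leaving out array 1 or array 2 gave 0 (234 and 239 at an unadjusted p under 0.05).

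Among the engineered loci, Trp53, the tumour suppressor mutated in these mice, lies on chromosome 11, called lower as a whole in array 4 (mean -0.41), with means of -0.13, -0.03 and -0.05 in arrays 1 to 3. Lower calls covered 68.9%, 19.3% and 0% of its bins in arrays 1 to 3. In array 1 higher calls covered 13.4% of them, so the mean of -0.13 joins opposite calls. Pdx1, the pancreatic transcription factor, lies on chromosome 5, which had no whole-chromosome call but was called in part. Higher calls covered 45.6%, 2.01%, 3.36% and 0% of the bins of chromosome 5 in arrays 1 to 4. Lower calls covered 0%, 4.70%, 4.70% and 0% of them. In array 3 chromosome 5 was at -0.95 from 147004639 to 152536960. Because the files name no genes, a gene is described here by its whole chromosome, and a smaller segment that covers it may differ.

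Of 35 tumour suppressors known in pancreatic cancer, 16 lay on a chromosome called lower as a whole in at least 1 array, 9 of them in at least 2, and none on a chromosome called higher. With mode centring 24 lay on a lower chromosome, 9 of them in at least 2 arrays. Chromosome 4 was lower in arrays 1 (-0.34) and 4 (-0.76). It carries the cell-cycle inhibitors Cdkn2a and Cdkn2b, the methionine salvage enzyme Mtap, the chromatin remodelling subunit Arid1a and the TGF-beta receptor Tgfbr1. In array 1 no segment of chromosome 4 was called between 87982594 and 89892074, and which listed genes lie there was not looked up. Chromosome 14, lower in arrays 1 (-0.33) and 2 (-0.64), carries the cell-cycle regulator Rb1, the deubiquitinase Bap1, the chromatin remodelling subunit Pbrm1 and Fhit, which spans a fragile site. In array 4 the lower chromosomes also carry Stk11 (chromosome 10) and the DNA repair genes Palb2 (chromosome 7) and Brca1 (chromosome 11). Chromosome 11 further carries the kinase Map2k4, Nf1 and the Wnt pathway inhibitor Rnf43. On chromosome 11 of array 4, 88 probes from 65107628 to 66197562 were at -5.99, and which listed genes lie there was not looked up. Counted by array, 9, 4, 0 and 12 suppressors lay on a lower chromosome. A further 5, Atm, Setd2, Smad3, Smarca4 and Tgfbr2, lie on chromosome 9, which passed limma without reaching 90% of its bins in any array. That chromosome was not lower throughout. Array 1 was at 0.54 from 4363298 to 9531072, and array 2 was at 0.26 from 20473339 to 22239949. Whether each listed gene of chromosome 9, oncogenes included, lies in a lower segment was not determined, since genes were placed by chromosome only.

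Among 27 oncogenes, the kinase Braf and the growth factor receptor Met lie on chromosome 6, called higher as a whole in arrays 1, 2 and 3, and in arrays 2 and 3 alone with mode centring or the authors' constants. On a chromosome called lower as a whole lay 12 oncogenes, or 15 with mode centring. These were Jun on chromosome 4, Akt1 and Mycn on chromosome 12 (lower in arrays 1 and 2), and in array 4 Cdk4, Mdm2, Akt2, Ccnd1, Ccne1, Hras, Egfr, Erbb2 and Sox9. On neither kind of chromosome lay 11. In all, 11 of the 62 suppressor and oncogene entries lay on the chromosomes past limma, 6 of them oncogenes, and 0 did with either of the alternative centrings or without array 1 or array 2. Leaving out array 3 gave 24, and leaving out array 4 gave 17. Of 20 comparison genes with no known link to the tumour, 4 lay on a higher chromosome, 6 on a lower one and 10 on neither, with 3 and 6 on a higher and a lower one under mode centring. The difference between lists was not tested, because genes of a chromosome share its value.

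The third comparison concerned focal changes, described by the 3 called segments under 3 Mb with the largest departure in each array, with mm9 positions and no replicate of any array. The strongest higher segment lay in array 3 on chromosome 5 from 145537959 to 146088854, at 2.495 (82 probes, SD over probes 0.20). A second, from 142269901 to 142407652, was at 2.28 (18 probes, SD 0.20). Chosen after their values were seen, 3 further segments were at 2.16 (139993791 to 140571437), 1.96 (142415880 to 143206006) and 1.90 (143515888 to 145532530), with uncalled stretches between some of them, and the chromosome beyond 147004639 was at -0.95 over 617 probes. Departure was measured from 0, so a segment within a longer lower stretch can differ little from its neighbours. In array 1, 114 probes on chromosome 9 from 46594287 to 48134938 were at -0.84 (SD 0.15), between called segments at -0.73 and -0.83. Also in array 1, 14 probes on chromosome 12 from 116233736 to 116350405 were at -0.84 (SD 0.31), between segments at -0.45 and -0.36. A longer segment on chromosome 12 of array 1, from 78356268 to 81684426 and also chosen after the values were seen, was at -1.75 over 369 probes. In array 2, 59 probes on chromosome 14 from 98175091 to 98581694 were at -1.04 (SD 0.15), between called segments at -0.72 and -0.64. Also in array 2, 5 probes on chromosome 11 from 121764074 to 121841954 were at -1.17 (SD 1.14).

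On chromosome 11, 10 neighbouring probes from 71001060 to 71107103 formed a segment with the same ends in 4 of 4 arrays. Their mean log2 ratios were -5.39, -5.25, -4.24 and -5.02 in arrays 1 to 4, a mean of -4.97 ± 0.51 (SD, n = 4). Their raw Cy5 signal was 1.11, 1.12, 1.29 and 1.09 times its background, so the ratios are bounded: Cy5 was at least 14.1-, 11.1-, 12.8- and 18.9-fold below Cy3. Cy3 was 5.47, 8.41, 9.79 and 8.44 times its background there, and 11.5, 15.2, 18.1 and 16.9 times over the 10 probes before the region. Those 10 probes had ratios of 0.60, -0.02, -0.01 and -0.42, and the 10 after it 0.63, -0.16, -0.04 and -0.43. The sign was the same in 4 of 4 arrays, for which an exact two-sided sign test cannot go below 0.125. Of the probes under -3 in all 4 arrays, 9 lay in this region and 0 elsewhere. With normexp background correction the mean was -1.39.

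In array 4, 88 probes on the same chromosome from 65107628 to 66197562 were at -5.99 (SD over probes 1.53), against -0.38, -0.26 and -0.09 in arrays 1 to 3. They were called as 3 neighbouring segments, at -5.61, -6.17 and -5.73, which were the strongest focal calls of array 4. Their Cy5 signal was 1.07 times background, with 67 of 88 probes not well above it, and Cy5 was at least 31.7-fold below Cy3. In array 1, by contrast, chromosome 11 was higher on both sides of the 10-probe region, at 0.73 from 70448994 to 70985090 and 0.74 from 71968507 to 80943552, both segments chosen after their values were seen.

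**Figure D3:**
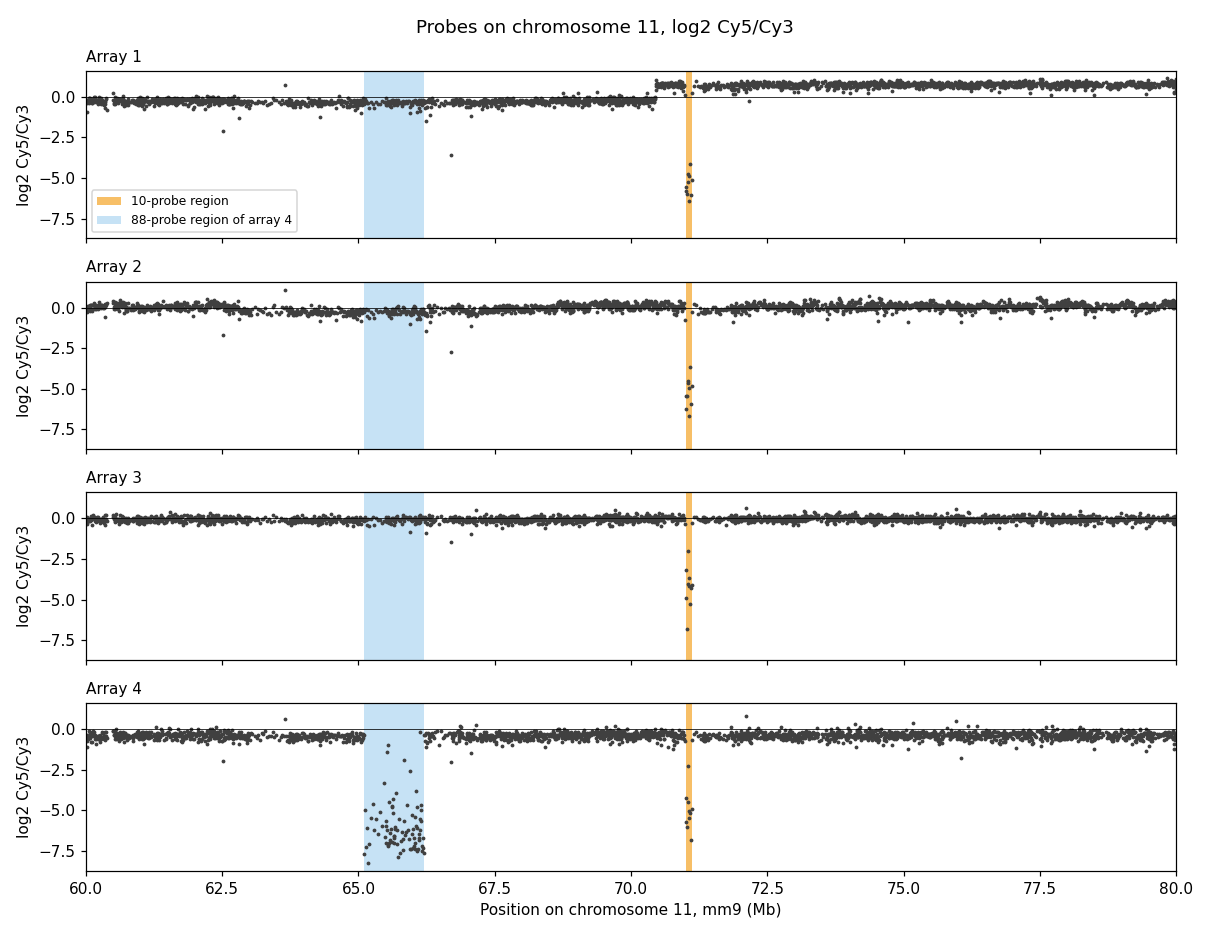
Log2 Cy5 over Cy3 of each probe (vertical axis, log2 units) by mm9 position in Mb (horizontal axis) on part of chromosome 11 for the 4 arrays, with the 10-probe region and the 88-probe region of array 4 shaded. The 10 probes average -5.39, -5.25, -4.24 and -5.02 in arrays 1 to 4, and the 88 probes fall to -5.99 in array 4 alone.

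The series title concerns germline variants that differ between mouse strains. The fourth comparison asked whether single probes depart from their segment more often on chromosomes 6 and 11, the pair set in the design, than on the other autosomes. The share of outlying probes there exceeded that on the other autosomes by 0.184 percentage points. This missed the threshold: 9 of the 171 choices of 2 autosomes gave as large a difference (exact permutation test, one-sided, p = 0.0526, smallest possible 0.0058). On chromosome 11, 0.817%, 0.537%, 0.208% and 0.585% of probes lay below their segment in arrays 1 to 4, a mean of 0.537% ± 0.251 (SD, n = 4). That was the highest of 19 autosomes in the mean and in arrays 1 and 2, while chromosome 6 was higher in array 3 (0.301%) and chromosome 4 in array 4 (0.720%). Chromosome 6 ranked 4, at a mean of 0.315% ± 0.109 (SD, n = 4). In array 1, 33 of these low probes lay between 50 and 60 Mb of chromosome 11, in array 2, 17 lay between 80 and 90 Mb, and in array 4, 32 lay between 60 and 70 Mb, a window that includes its 88-probe region. The test passed without array 4 (0.174 percentage points, exact permutation p = 0.0175) and with normexp background correction (0.314, p = 0.0058). Without the probes of segments below -3, a setting chosen after seeing the data, it gave 0.112 (exact permutation p = 0.164).

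Gene families known to vary in copy number between inbred strains numbered 2456 genes in the GRCm38.p6 table, of which 206 lie on chromosome 6 and 130 on chromosome 11, or 13.7%, against 12.01% of all 49554 genes in the table on these 20 chromosomes. Of the 25 families, 12 have no member on either, among them Skint, Defa, Defb, Gbp and H2-. All members of the natural killer receptor families Klra (16 genes), Klrb (6), Klrc (3) and Klri (2), all 9 Clec2 genes and 38 of 40 Tas2r taste receptors lie on chromosome 6. On chromosome 11 lie 10 of 11 Slfn genes, 12 of 29 Ccl chemokines and 3 of 6 genes whose symbol starts with Nlrp1. Their ratios could not be formed from the files.

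The last comparison asked how alike the 4 profiles were over the bins, which are not independent replicates. Arrays 1 and 2 were the most alike (Pearson 0.711, Spearman 0.717), followed by arrays 1 and 4 (0.512 and 0.578), 2 and 3 (0.401 and 0.377), 1 and 3 (0.330 and 0.314) and 2 and 4 (0.329 and 0.461). Of the 6 pairs, 4 had a rotation permutation p of 0.001, the smallest possible, and 0.0015 after adjustment, and arrays 1 and 3 had 0.006 and 0.0072. Arrays 3 and 4 did not pass (Pearson 0.156, Spearman 0.244, permutation p = 0.229 before and after adjustment). After each array's chromosome medians were subtracted, arrays 1, 2 and 4 still correlated along the chromosomes (Pearson 0.489, 0.464 and 0.455), and pairs with array 3 were lower, between 0.0516 and 0.112 (Spearman 0.181 to 0.284). All 6 pairs passed there, with rotation permutation p adjusted to at most 0.029.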

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

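In this part, the 88-probe region was picked after its values were seen, and no test was run beyond setting each array against the other 3. Of 29 sets of 4 values, 3 had an array far from the others by Dixon's test, where chance gives about 1 in 20. That rate does not apply to the 88-probe region, which was picked because array 4 stood apart there, and the other 2 sets are of the same array. The Cy3 signal of chromosome Y probes was 2.12% of the autosomal median in array 1 and 32.4% to 37.8% in the other 3. The Cy3 signal of chromosome X probes was 85.6% of the autosomal median in array 1 and 42.7% to 45.8% in the other 3. The 88 probes on chromosome 11 had a mean log2 ratio of -5.99 in array 4 and of -0.38 to -0.09 in the other 3.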

How the results depend on the processing

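The alternatives chosen after the data were seen were the authors' constants, the segments below -3 left out, correlations within chromosomes, whole-chromosome calls and list counts under other centrings, and those for chromosome means and the 10-probe region. Of 95 alternative values, 69 stayed on their side of the threshold or within the spread, and 0 reversed. Reversal means a change of sign, which counts and shares cannot show. The 69 include the turned sign and the authors' table centred again, which could hardly differ. The altered share stayed within the wide SD between mice (16.1) in each alternative. It still depended on the threshold, from 14.1% (threshold 0.40) to 42.1% (threshold 0.15), and was 24.0% to 35.4% without an array. The correlation of profiles stayed within its SD over the pairs of arrays, at 0.296 to 0.517 without an array. Cy5 carried the larger part in every array at each threshold. Recurrence counted 582 bins at a threshold of 0.15, 75 at 0.40 and 58 of 537 with 5-Mb bins, and 382 to 850 without an array, where 2 of 3 arrays were asked for. Each passed its rotation test. Outlying probes on chromosomes 6 and 11 passed with normexp (0.314 percentage points), a penalty of 10 (0.180) and a limit of 6 SDs (0.102), and ranged from 0.157 to 0.220 without an array, passing without array 4. By limma, array weights raised the called bins from 0 to 514, and leaving out an array gave 0 to 429; the count stayed 0 with normexp, mode centring, the authors' constants, bright probes and 5-Mb bins (620, 518, 468, 600 and 126 unadjusted). With mode centring or the authors' constants, 0 chromosomes and 0 list genes passed (limma, 5 and 3 chromosomes at an unadjusted p under 0.05); leaving out an array gave 0 to 5 chromosomes and 0 to 24 list genes. The 10-probe region was at -1.39 with normexp, whose offset of 50 is added to both channels and so limits ratios near background, and at -5.22 to -4.84 without an array. Apart from that offset, the bin size, the thresholds and the 2 of 3 arrays, the cause was not tested. No paired analysis was possible because there is 1 group, and each array already pairs a culture with its tail. The authors' table, centred again on its median, gave the same altered share (13.5%), recurrence (30 bins) and correlation (0.283) as the scanner values on chromosomes 1 to 5. Its values differ from the scanner values by little more than 1 constant per array, which that centring removes. The equality is therefore no independent check. The table was not run for outlying probes and gene lists, which need other chromosomes. Correction for GC content was not run. Cy5 signal over background, 1.09 to 1.29 in the 10-probe region, limits its ratio to a bound.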

Other observations

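In this part, the tests of the 10-probe region, of the high probes of array 4 and of sign patterns were chosen after the results were seen, and those of the correlation within chromosomes before, although that correlation was itself added after seeing the data. Chromosome Y probes had median log2 ratios of -1.05, -0.02 and 0.20 in arrays 2 to 4. In array 1 their signal was 2.12% (Cy3) and 1.38% (Cy5) of the autosomal median, too low for a ratio, and the sex of the mice is not given in the sources used here. Chromosome X probes had 0.10, 0.23, 0.04 and 0.14 in arrays 1 to 4. In array 4, 22 probes on chromosome 18 from 26841989 to 27261540 and 10 probes from 27851691 to 28075139 were at -1.60, and 608 probes on chromosome 11 from 3100146 to 8906087 were at 0.83. In array 1, 122 probes on chromosome 19 from 45898214 to 46698034 were at 0.79. In array 3, 6 separate called segments on chromosome 4 between 102936815 and 120071750 were at 0.26 to 0.51, with uncalled stretches between them.

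The 10 probes on chromosome 11 were near Cy5 background in every array. Probes that fail in the Cy5 channel are argued against by the 0 probes outside the region under -3 in all 4 arrays, and separate deletions with chance ends by the 4 arrays with the same pair of end probes. An inherited deletion on a chromosome 11 haplotype that the mice share, exposed where the culture lost the other haplotype, remains a hypothesis: probes outlying low in at least 3 arrays numbered 24.1 per 10000 within 10 Mb of the region (6 of 2489), above each of 2056 other overlapping windows, where the highest was 21.2 and the median 4.85. That margin is small, and ratios beside the region, 0.60 and 0.63 in array 1 and -0.16 to -0.01 in arrays 2 and 3, show no lower copy number there in 3 of 4 arrays. The explanation may hold in those 3 only if the lost haplotype was replaced by the other, and strain genotypes were not analysed here.

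On the 4 chromosomes called lower as a whole in array 4, 50478 probes lay in segments called lower but above -3. Of these, 281 (0.557%) lay above their segment, against 0.050% of all probes on its other autosomes. The exact permutation test, over 3876 choices of 4 autosomes with all probes of each, gave a one-sided p = 0.000258, the smallest possible. Below their segment lay 250 of the 50478 (0.495%, against 0.237%). Of the 281, 91.5% (95% exact Clopper-Pearson interval 87.6% to 94.5%) were in the top 10% of these chromosomes' probes by the Cy3 difference between array 3 and arrays 1 and 2, and their median Cy3 signal lay 1.05 and 1.43 above the array median in arrays 4 and 3 and 0.15 and 0.22 above it in arrays 1 and 2 (log2). Extra signal at a subset of probes in arrays 3 and 4, pulling ratios toward 0, may give this share but not the low probes, and strain variants exposed by loss of a parental chromosome may give both if mice 3 and 4 share alleles that mice 1 and 2 lack. Without strain genotypes, which were not analysed here, these explanations cannot be told apart.

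Arrays 1, 2 and 4 correlated along the chromosomes. Over bins called in neither array of a pair, their mean Pearson correlation was 0.672, against 0.261 for the pairs with array 3. This argues against shared called changes as the only cause. Bins that were not called can hold changes below the call threshold, so the test cannot exclude smaller shared changes. Nor can it show what called changes add over all bins. A wave along the chromosomes that is independent of called changes also predicts a correlation over uncalled bins. More DNA from early-replicating regions in growing cultures predicts a rise with the number of probes per bin, and the mean Spearman rho was 0.411 in arrays 1, 2 and 4 (-0.143 in array 3). GC content predicts the same rise and could not be measured here, so these sources of such a wave cannot be told apart.

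For the limma counts, the 4 arrays allow 8 patterns of signs up to a mirror image, too few for a share under 0.05. For bins, 8 of 8 patterns gave as many calls, with 0 in the real pattern and 0 as the highest of the others (599 and 296 at an unadjusted p under 0.05). For chromosomes, 1 of 8 patterns gave as many, the real one, with 2 calls and 0 as the highest of the others (6 and 3 unadjusted).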
